A study of Homo sapiens with 12 samples.

How the data were processed

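The study measured gene expression by RNA sequencing in AC16 cells, a human line with features of ventricular cardiomyocytes. Recombinant interferon alpha-2a, a type I interferon, was added at 1000 U/mL, per the labels' protocols. There were 4 groups of 3 libraries each. Vehicle cells received phosphate-buffered saline and carry a 24 h label. Acute cells were harvested at the end of a 24 h pulse of interferon. Recovery cells received the same 24 h pulse and were then kept 5 days without interferon, with harvest on day 6. Repeat cells received a 24 h pulse, 4 days without interferon and another 24 h pulse. Their labels place harvest on day 7, while the stated times add to 6 days. Per the labels' protocols the libraries were poly(A)-selected and stranded, made from 325 ng of RNA with a RIN of at least 8 and 12 PCR cycles, and read as single 75 bp reads with 30 M reads (1 M is 1000000) planned per library. All 12 libraries carry the same batch label. The design text states that the replicates are independent biological replicates.

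The labels contradict each other in several places. The design text and the growth protocol name different media (DMEM/F-12 and an RPMI medium). The design text says that vehicle was given for equivalent intervals, but every vehicle library is labelled 24 h. Comparisons of recovery or repeat with vehicle, and of either with acute, are therefore also comparisons of time in culture as labelled. The design text names DESeq2, whereas the submitters' processing notes name edgeR.

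Reads were processed by the authors before deposit. Per the submitters' processing notes the tools were Trim Galore 0.6.10, cutadapt 4.3, STAR 2.7.11a, Picard 2.27.5, featureCounts 2.0.3 and edgeR, with genome build GRCh38.p13. Per the design text in the labels the annotation was GENCODE release 41. The roles, order and parameters of these tools, including whether counting used the strand of the reads, are not given in the sources used here. The authors deposited one table of estimated counts per gene, not scaled between libraries, and one table of TPM (counts scaled by gene length) summing to 1000000 per library. Both hold 60649 gene identifiers, of which 36621 had a count in at least 1 library. Although featureCounts normally gives whole numbers, 25.49% of the nonzero values in the deposited count table were not whole. The gene length implied by counts and TPM also varied over libraries, with a median coefficient of variation of 4.35% over 9015 genes with at least 500 counts. The values were therefore treated as estimated counts and rounded to whole numbers. TPM columns each summed to 1000000. Gene symbols and coordinates came from GENCODE release 44 on GRCh38, in which 60507 identifiers were matched. No column was without a sample (0 such columns).

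Total estimated counts per library were 56.7, 43.8 and 45.8 M for vehicle, 56.5, 39.9 and 43.4 M for acute, 44.4, 46.0 and 48.4 M for recovery, and 54.7, 62.3 and 48.8 M for repeat. Replicate libraries differed by more than sampling noise: over genes with a mean of at least 50 counts the median squared difference was 1.77 to 3.02 times that of Poisson counts. This check used unscaled library totals, and it cannot show that replicates came from separate cultures. No pair was counted as 1 sample. P-values here measure differences against the spread among these libraries, a biological coefficient of variation of 2.67%. They would be too small if replicates shared a culture.

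The test, its samples, the gene lists, the rule for named genes and all but 3 of the alternatives were chosen before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test (robust fit, TMM scaling, filterByExpr with the 4 groups). All 12 libraries entered 1 fit with a mean per group and no covariate. The filter kept 18119 genes, and the common biological coefficient of variation was 2.67%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. Errors of log2 fold changes are standard errors of the fit. Errors of CPM (counts per 1000000, TMM-scaled) are SDs over 3 libraries. Log CPM for the principal components used a prior count of 2. The 6 pairwise comparisons were made. The interaction compared the response to the later pulse (repeat minus recovery) with the response to the first (acute minus vehicle). Genes changed beyond 1.5-fold were counted with glmTreat.

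Gene lists numbered 33. They covered classical interferon-stimulated genes; interferon receptor, JAK-STAT and IRF components; negative regulators of interferon signalling; nucleic acid sensing; MHC class I; MHC class II; interferon-gamma-type genes; inflammatory cytokines and NF-kB targets; complement; cell death; G1/S; G2/M; nuclear-encoded oxidative phosphorylation; mitochondrially encoded mRNAs; glycolysis; fatty acid oxidation; cholesterol synthesis and uptake; amino acid and endoplasmic reticulum stress; heat shock; p53 targets; hypoxia; NRF2 targets; cardiomyocyte, endothelial, leukocyte and epithelial markers; fibroblast and matrix genes; TGF-beta and YAP targets; replication-dependent histones; lupus and Sjogren autoantigens; tryptophan and NAD metabolism; long noncoding RNAs near interferon genes; and retroelement restriction factors. SOD2, in the NF-kB list, was not matched. Lists were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01 and again with a correlation estimated per list. Fry tested each list against no change, which is another question. P-values were adjusted over the 33 lists within a comparison. Members called are given over all genes tested and adjusted over the list alone.

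Named genes followed a rule. For each comparison it took up to 10 rises and 10 falls, largest first, among called genes with a gene symbol (not only an Ensembl identifier), a mean of at least 5 CPM in the higher group and no overlap between the 3 libraries of each group (overlap was allowed for the interaction). It added up to 4 members per list with the smallest p, called or not. STAT2, IRF9, IRF7, IRF1, ISG15, IFI27, USP18, SOCS1, CXCL10, IFNAR1, IFNAR2, B2M, TNNT2, NPPB and MKI67 were among those always eligible. The text names genes from the top of each ranking.

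The share of an acute rise that remained in recovery was computed from mean CPM as (recovery minus vehicle) over (acute minus vehicle). Recovery and acute were both compared with the same vehicle libraries. In 20 simulations unchanged groups were drawn around the observed means of these vehicle libraries. Error in those means is then not common to both comparisons, so the simulations cannot give the chance correlation from this sharing. With 3 vehicle libraries, a split of the controls would leave fewer than 2 in 1 part and was not made.

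The edgeR steps were tested on simulated data with the real means and library sizes, 18119 genes and 200 changed genes, 50 at each fold. The changed genes were drawn from those with a mean of at least 1 CPM. The shares recovered are therefore not known for genes with fewer counts. At 1.2-fold the share recovered was 70% for acute against vehicle, 64% for recovery against vehicle, 66% for repeat against vehicle, 68% for recovery against acute, 70% for repeat against recovery, 66% for repeat against acute and 54% for the interaction. At 1.5-fold it was 90%, 86%, 88%, 88%, 88%, 92% and 82% in the same order.

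Alternatives were DESeq2 1.42.0 (on all genes, with its own independent filtering in place of the count filter), limma-voom, RLE and upper quartile scaling, no count filter, a filter of 1 CPM in 3 libraries, limma-trend on log2(TPM + 1), the replicate number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01, a fit of only the groups compared, and leaving out each of the 12 libraries. Chosen after seeing the data were an offset for the implied gene length, library depth as a covariate, and the slope over genes with a vehicle mean of at least 1 CPM. DESeq2 gave some genes no adjusted p, and these were counted as not called by it. Of 263 named results the DESeq2 call was the same in 242 and lost in 3, and the rest had no adjusted p. Protein data and reads were not used here.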

Results

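RNA sequencing was used to measure how AC16 cells, a human cell line with features of ventricular cardiomyocytes, responded to a pulse of interferon alpha-2a, how far they returned afterwards, and how they responded to another pulse. The design text places the work in the setting of systemic lupus, in which type I interferon is raised. Each of the 4 groups (vehicle, acute, recovery and repeat) held 3 libraries from cultures stated to be independent biological replicates. Total estimated counts ranged from 39.9 to 62.3 M per library, and 18119 genes passed the count filter. The first principal component of log CPM held 40% of the variance and placed the 6 libraries harvested right after a pulse at 27.6 to 31.9, away from the vehicle and recovery libraries at -36.5 to -25.7. The next component held 8.05% and spread libraries within groups, with 1 acute library lowest at -31.0. Of 32 cardiomyocyte markers 15 passed the filter. TNNT2, which encodes cardiac troponin T, had 14, 3 and 3 counts in the vehicle libraries and at most 3 in any other, below the filter.

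**Figure D1:**
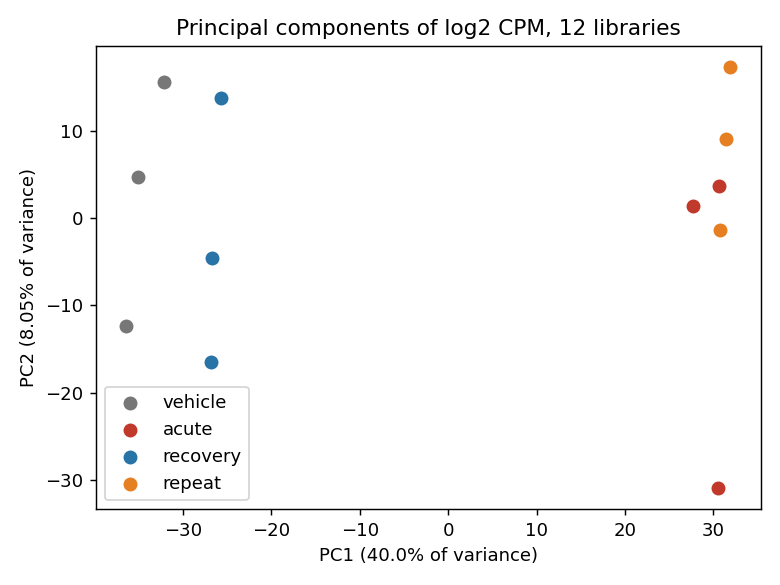
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis and colours for the 4 groups. Acute and repeat libraries lie at one end of the first axis (27.6 to 31.9) and vehicle and recovery libraries at the other (-36.5 to -25.7).

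The first comparison asked what 24 h of interferon did. Antiviral effector genes rose most. MX1, a GTPase that blocks virus replication, went from 3.55 ± 0.977 CPM in vehicle to 772 ± 9.05 CPM in acute cells (SD, n = 3 each), a log2 fold change of 7.73 ± 0.078 (adjusted p = 6.89e-14, edgeR quasi-likelihood test). Its relative MX2 rose by 9.42 ± 0.131 on the log2 scale. OAS1 and OAS2, sensors of double-stranded RNA that activate RNase L, rose by 8.97 ± 0.066 and 7.54 ± 0.038. IFI44L rose by 8.57 ± 0.065, BST2, which tethers budding virions, by 8.16 ± 0.10, and IFI27, often used in interferon signatures of blood, by 8.08 ± 0.085. USP18, which damps signalling at the interferon receptor, rose by 6.60 ± 0.092, the nucleotide kinase CMPK2 by 6.31 ± 0.107, and IFITM1, which restricts virus entry, by 5.86 ± 0.064. Every one of the 60 classical interferon-stimulated genes measured rose, over all genes tested and adjusted over the list alone, with a median log2 fold change of 2.88. Camera called the list at an adjusted p of 1.15e-72, and at adjusted p = 0.00165 with an estimated correlation. OAS3 (5.16 ± 0.030) and PARP9 (3.82 ± 0.033) were among its members. USP18 has a near-identical copy, USP41, and IFITM and HLA genes have close relatives, so reads may have been split between copies and their single values are uncertain. On GRCh38 with GENCODE release 44, MX1 (ENSG00000157601.15) lies on the plus strand of chromosome 21 at 41420020 to 41470071, OAS2 (ENSG00000111335.14) on the plus strand of chromosome 12 at 112978395 to 113011723, and IFI27 (ENSG00000165949.12) on the plus strand of chromosome 14 at 94104836 to 94116695.

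The factors that carry the interferon signal rose as well. STAT2 and IRF9, parts of the ISGF3 complex, rose by 1.72 ± 0.035 and 2.33 ± 0.034, and the transcription factors IRF7 and IRF1 by 3.39 ± 0.048 and 0.58 ± 0.044. Of 19 receptor, JAK-STAT and IRF components, 11 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.000805). That call was lost at adjusted p = 0.0518 with an estimated correlation. The receptor genes moved little: IFNAR1 had a log2 fold change of -0.08 ± 0.027 (adjusted p = 0.0203) that turned to 0.08 on log2 TPM and 0.07 with the gene length offset, uncalled in both, and IFNAR2 one of 0.06 ± 0.054 (adjusted p = 0.398). ISG15, a ubiquitin-like modifier, rose by 3.93 ± 0.033, and SOCS1, an inhibitor of JAK kinases, by 1.03 ± 0.11. CXCL10, a chemokine, stayed near the floor at 0.213 CPM, with a log2 fold change of 1.78 ± 0.595 (adjusted p = 0.0164) that DESeq2 and the gene length offset did not call.

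Antigen presentation and RNA sensing rose in the same cells. All 22 genes of MHC class I presentation rose, also adjusted over the list alone, with a median of 1.21 (camera adjusted p = 1.25e-28; 0.00165 with an estimated correlation). The peptide transporters TAP1 and TAP2 rose by 2.92 ± 0.029 and 2.10 ± 0.024, HLA-C by 1.71 ± 0.022 and B2M, the shared light chain, by 1.36 ± 0.021. Nucleic acid sensing had 18 of 20 members higher and 1 lower (the same counts adjusted over the list alone), and held with an estimated correlation at adjusted p = 0.00188. SAMHD1, which depletes nucleotides, rose by 2.71 ± 0.027, the DNA sensor IFI16 by 1.88 ± 0.021 and the RNA editor ADAR by 1.45 ± 0.021. Interferon-gamma-type genes rose in 19 of 20 cases (19 adjusted over the list alone; adjusted p = 0.00626 with an estimated correlation), among them GBP1 (2.10 ± 0.031) and APOL6 (2.04 ± 0.040). Retroelement restriction factors rose in 11 of 13 cases and fell in 1, unchanged when adjusted over the list alone (adjusted p = 0.00188 with an estimated correlation); ZC3HAV1, which binds CpG-rich RNA, rose by 1.00 ± 0.028.

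Inflammatory and secreted factors moved with them. Of 21 NF-kB targets and cytokines, 16 rose and 1 fell (17 and 1 adjusted over the list alone), including BIRC3, an inhibitor of apoptosis (1.46 ± 0.066), and the cytokines LIF (1.05 ± 0.048), IL11 (0.76 ± 0.042) and CXCL8 (1.51 ± 0.096). The camera call (adjusted p = 7.26e-07) was lost at adjusted p = 0.0518 with an estimated correlation. Complement had 7 of 13 higher and 1 lower (7 and 1 adjusted over the list alone), led by the proteases C1S (1.70 ± 0.040) and C1R (1.33 ± 0.034) and by CFB (1.59 ± 0.061); its call (adjusted p = 0.00164) was lost at adjusted p = 0.13 with an estimated correlation. Among 24 cell death genes 16 rose and 4 fell (16 and 5 adjusted over the list alone), with the BH3 protein PMAIP1 at 1.30 ± 0.033 and the necroptosis effector MLKL at 1.56 ± 0.063. This call (adjusted p = 9.48e-05) was lost at adjusted p = 0.0518 with an estimated correlation. TGF-beta and YAP targets had 12 of 22 higher and 5 lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.000816), lost at adjusted p = 0.149 with an estimated correlation. ANKRD1, a stress-responsive muscle gene, rose by 2.07 ± 0.072 and the activin subunit INHBA by 1.31 ± 0.032. Heat shock genes rose in 9 of 13 cases (9 adjusted over the list alone), with DNAJA1 at 0.47 ± 0.023 and HSPA8 at 0.23 ± 0.020; the call (adjusted p = 0.00146) was lost at adjusted p = 0.163 with an estimated correlation.

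**Figure D2:**
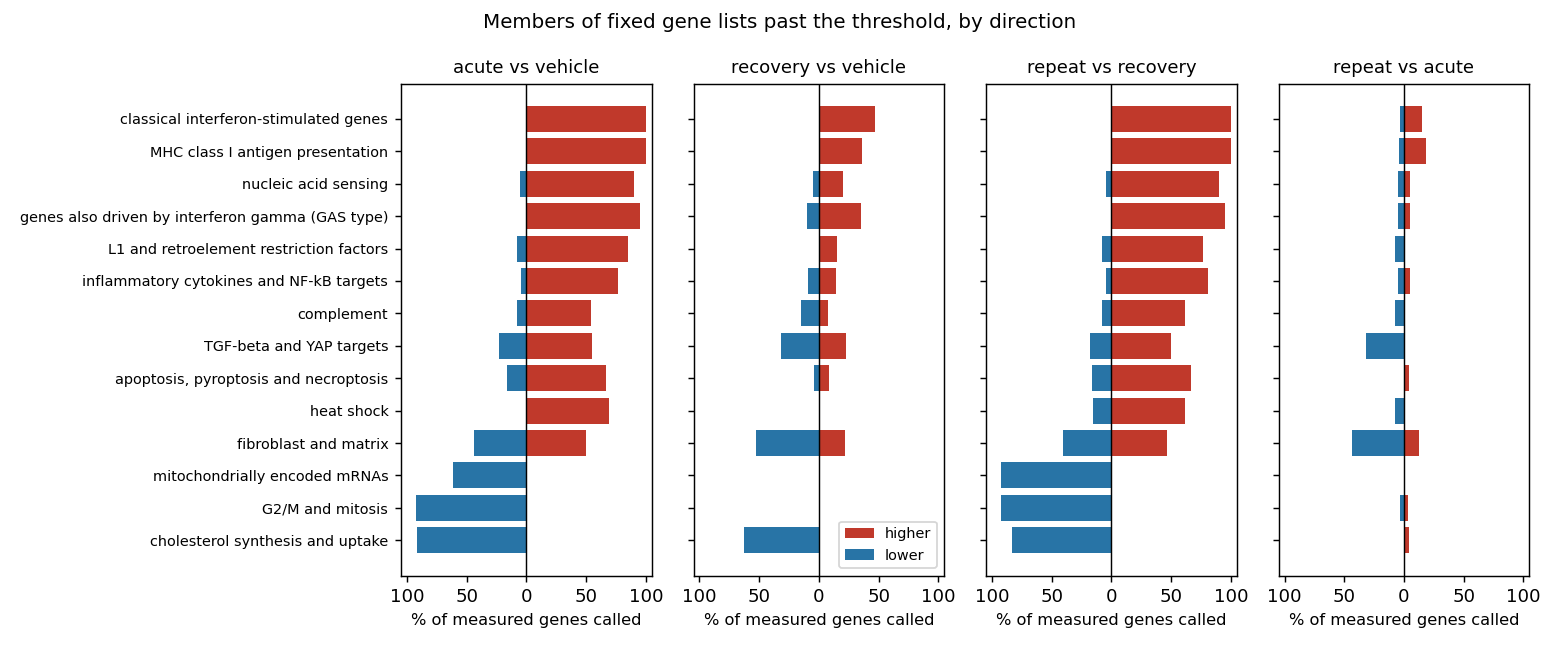
Percent of measured members of 14 gene lists called higher (right, red) and lower (left, blue) in 4 comparisons, 1 panel each. Interferon-stimulated and MHC class I genes all rose in acute against vehicle and in repeat against recovery, where most G2/M, cholesterol and mitochondrially encoded genes fell.

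Fewer genes fell strongly. TNFRSF10D (ENSG00000173530.6, minus strand of chromosome 8, 23135588 to 23164027), a decoy receptor for the death ligand TRAIL, went from 121 ± 5.99 to 12.5 ± 0.331 CPM, a log2 fold change of -3.27 ± 0.039. The retinal reductase DHRS3 (-2.51 ± 0.099), the scavenger receptor COLEC12 (-2.43 ± 0.118), MTURN (-1.72 ± 0.070), LINC00641 (-1.65 ± 0.102) and CASTOR2, an arginine-sensor relative (-1.53 ± 0.065), followed. SCD, which makes monounsaturated fatty acids, went from 1263 ± 136 to 445 ± 7.78 CPM (-1.51 ± 0.082). DEPTOR, an inhibitor of mTOR (-1.47 ± 0.121), the cholesterol exporter ABCA1 (-1.47 ± 0.131) and ACO1, an iron-responsive aconitase (-1.45 ± 0.026), completed the 10 largest falls among genes with a symbol, at least 5 CPM in vehicle and no overlap between the groups. Cholesterol synthesis and uptake fell in 22 of 24 cases (23 adjusted over the list alone), with LSS at -0.83 ± 0.029, IDI1 at -0.52 ± 0.025 and the regulator SREBF2 at -0.47 ± 0.023. Its camera call (adjusted p = 4.17e-15) was lost at adjusted p = 0.125 with an estimated correlation. Genes of G2/M and mitosis fell in 26 of 28 cases (26 adjusted over the list alone) by small amounts (median -0.24), and this held at adjusted p = 0.0021 with an estimated correlation. The motor KIF20A fell by 0.43 on the log2 scale (SE 0.022), TOP2A by 0.41 and PLK1 by 0.32, while the proliferation marker MKI67 had -0.20 ± 0.031 (adjusted p = 5.2e-05). G1/S genes fell in 14 of 25 cases and rose in 3 (14 and 4 adjusted over the list alone), with the cell cycle factor E2F1 at -0.33 ± 0.027; the call (adjusted p = 0.00448) was lost at adjusted p = 0.158 with an estimated correlation. Mitochondrially encoded mRNAs fell in 8 of 13 cases (8 adjusted over the list alone), MT-CO3 by 0.57 and MT-ATP6 by 0.44 on the log2 scale (camera adjusted p = 9.48e-05, lost at adjusted p = 0.312 with an estimated correlation). All genes with an MT- symbol, not only these mRNAs, held 5.64% ± 0.173 of counts in vehicle and 4.70% ± 0.15 in acute libraries (SD, n = 3 each). The difference was -0.942 percentage points (exact two-sided permutation p = 0.1, the smallest that 20 permutations allow). The fibroblast and matrix list went both ways, 16 higher and 14 lower of 32 (the same counts adjusted over the list alone; camera adjusted p = 0.947), and the stromal surface genes PDGFRB (-0.58 ± 0.029) and FAP (-0.65 ± 0.034) were among those that fell.

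In all, 7940 genes passed the threshold between acute and vehicle cells, 4050 higher and 3890 lower. The changes were mostly small: 386 rose and 202 fell at least 2-fold, and 548 changed beyond 1.5-fold by glmTreat. With upper quartile scaling 7940 passed, but split 3462 higher and 4478 lower, so which direction held more genes depended on the scaling. On log2 TPM 4344 genes passed and with an offset for the implied gene length 4405, but of the 95 genes named as changed in this comparison 93 and 92 were called in the same direction in those fits.

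**Figure D3:**
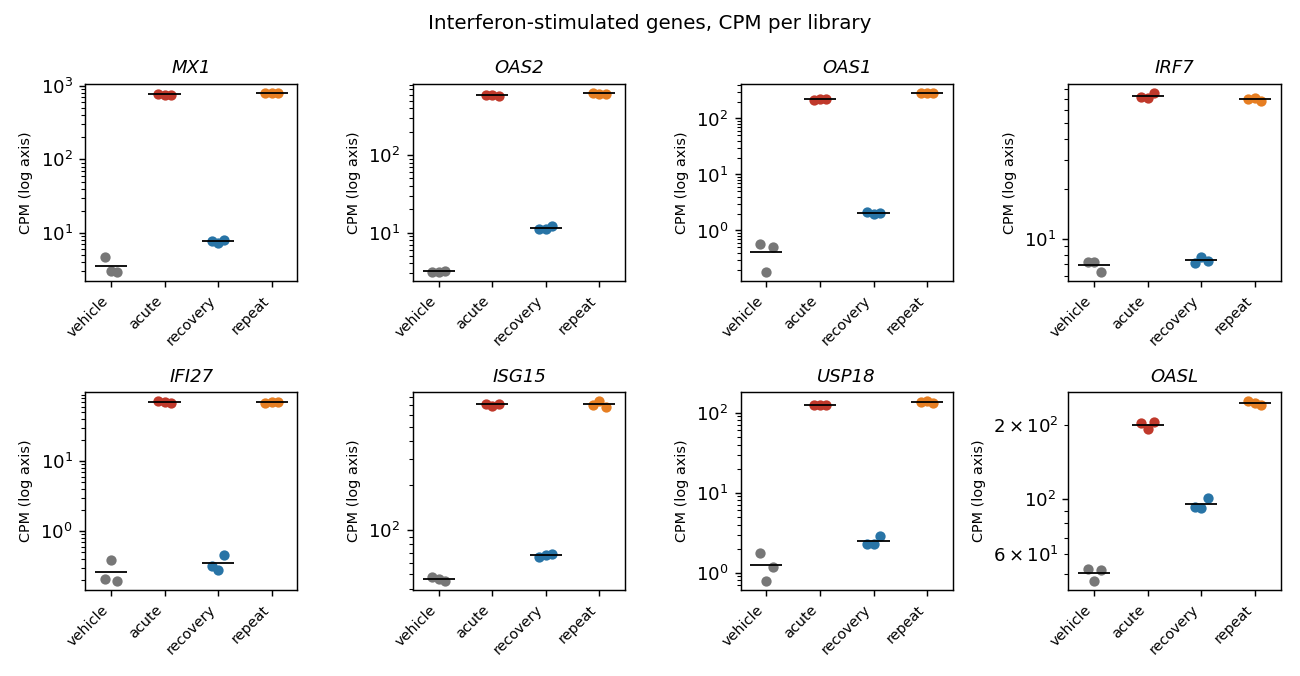
CPM on log axes, scaled per gene, of MX1, OAS2, OAS1, IRF7, IFI27, ISG15, USP18 and OASL in the 4 groups; points are libraries (n = 3) and lines are means. Levels rise in acute and repeat cells and drop again in recovery, where OAS2 (11.4 against 3.15 CPM) and OASL (95.4 against 50.3 CPM) stay above vehicle.

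The return after the pulse was followed by comparing recovery with acute cells. IFI44L fell by 8.02 on the log2 scale (SE 0.062), BST2 by 7.75, IFI27 by 7.64 and OAS1 by 6.74, while MX1 changed by -6.65 ± 0.071 and MX2 by -6.53 ± 0.097. Genes that had fallen came back, with TNFRSF10D higher by 3.10 ± 0.040, COLEC12 by 2.28 ± 0.119, DHRS3 by 2.06 ± 0.102 and MTURN by 1.67 ± 0.071. All 60 interferon-stimulated genes and all 22 MHC class I genes fell, also adjusted over the list alone, and 27 of 28 G2/M genes rose (27 adjusted over the list alone). These 3 lists held with an estimated correlation, each at adjusted p = 0.00125. Cholesterol genes rose in 20 of 24 cases and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation). Mitochondrially encoded mRNAs rose in 9 of 13 cases (10 adjusted over the list alone, camera adjusted p = 0.184 with an estimated correlation). All genes with an MT- symbol held 5.64% ± 0.059 of counts in recovery libraries. The edgeR test called 7448 genes, 3696 higher and 3752 lower. On log2 TPM 3836 passed, split 1514 higher and 2322 lower, and with the gene length offset 3946. Upper quartile scaling split its calls 4329 higher and 3149 lower. Recovery and acute cells also differ in time in culture, so the return is not shown to come from the loss of interferon alone.

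What remained 5 days after the pulse was tested by comparing recovery with vehicle cells. Most interferon genes were back near the vehicle level, but some antiviral genes were not. OAS2 stood at 11.4 ± 0.741 CPM against 3.15 ± 0.065 in vehicle (log2 fold change 1.86 ± 0.061, adjusted p = 6.97e-18), against 587 at the end of the pulse. MX1 was higher by 1.08 ± 0.137 (adjusted p = 0.00102), and OASL, an OAS relative that boosts RNA sensing (ENSG00000135114.13, minus strand of chromosome 12, 121017763 to 121039246), by 0.92 ± 0.047. The guanylate-binding protein GBP4 was higher by 0.91 ± 0.096. Its mean of 8.07 CPM in recovery lay above the 7.08 CPM in acute cells, so this difference may not be only a remainder of the acute rise. Of the 60 interferon-stimulated genes, 28 were higher and 0 lower over all genes, and 31 were higher adjusted over the list alone. For the 0, DESeq2, limma-voom and the TPM fit also gave 0 lower, and 31 members had an unadjusted p under 0.05. The list's median was 0.17 (camera adjusted p = 4.56e-24), lost at adjusted p = 0.0632 with an estimated correlation. OAS3 (0.58 ± 0.032), IFI44 (0.56 ± 0.035), ISG15 (0.53 ± 0.035) and USP18 (0.95 ± 0.197, adjusted p = 0.0123) were higher. IFI27 (0.44 ± 0.29, adjusted p = 0.503), STAT2 (-0.11, adjusted p = 0.0952), IRF9 (-0.14, adjusted p = 0.0586) and IRF7 (0.10, adjusted p = 0.529) did not pass, and IRF1 was higher by 0.16 ± 0.046 (adjusted p = 0.0392), a call lost by DESeq2, on log2 TPM and with the gene length offset.

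MHC class I genes were higher in 8 of 22 cases (12 adjusted over the list alone), with HLA-C at 0.23 ± 0.022, HLA-F at 0.92 ± 0.106, HLA-B at 0.24 ± 0.027 and B2M at 0.12. The call (adjusted p = 1.53e-09) was lost at adjusted p = 0.0632 with an estimated correlation. Nucleic acid sensing had 4 of 20 higher and 1 lower (6 and 3 adjusted over the list alone), with STING1 (0.34 ± 0.037) and RIGI (0.55 ± 0.053) higher and IFI16 lower (-0.11 ± 0.022); its adjusted p of 0.0474 became adjusted p = 0.297 with an estimated correlation. Interferon-gamma-type genes had 7 of 20 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with ICAM1, an adhesion molecule, lower (-0.43 ± 0.042). Retroelement restriction factors had 2 of 13 higher (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), with ZC3HAV1 at 0.27 ± 0.029. JAK-STAT components had 1 of 19 higher and 2 lower (2 and 8 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), with STAT3 at -0.14 ± 0.026.

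Other genes higher in recovery were not classical interferon targets. SFRP1, a secreted Wnt antagonist (ENSG00000104332.12, minus strand of chromosome 8, 41261962 to 41309473), was at 109 ± 5.35 CPM against 61.8 ± 1.42 in vehicle (0.81 ± 0.031, adjusted p = 1.68e-16), although acute cells had 65.8 ± 1.51. The collagen receptor ITGA2 was higher by 0.86 ± 0.077, the BMP target ID1 by 0.75 ± 0.099, SCUBE3 by 0.71 ± 0.062, LYPD1 by 0.71 ± 0.077 and PLXNA2, a semaphorin receptor, by 0.70 ± 0.078. Among genes with a symbol and at least 5 CPM without overlap between the groups, the largest falls were in TENM2, a teneurin adhesion protein (-0.71 ± 0.048), IGFBP5 (-0.69 ± 0.11), DEPTOR (-0.67 ± 0.114), the collagen-binding proteoglycan LUM (-0.66 ± 0.061), OLR1 (-0.64 ± 0.111), ABCA1 (-0.60 ± 0.122), the matricellular protein POSTN (-0.60 ± 0.041), ECEL1P2 (-0.57 ± 0.081), LYPD6B (-0.57 ± 0.074) and SCD (-0.57 ± 0.080). Cardiac stress and sarcomere genes were scarce: NPPB, which encodes the natriuretic peptide BNP, was at 0.158 ± 0.038 CPM against 0.519 ± 0.112 (-1.71 ± 0.342, adjusted p = 0.00154, not called by DESeq2), and ACTN2 was higher by 0.99 ± 0.14.

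Matrix genes were mostly lower. Of 32 fibroblast and matrix genes, 17 fell and 7 rose (18 and 7 adjusted over the list alone; camera adjusted p = 3.49e-08), a call lost at adjusted p = 0.0921 with an estimated correlation. POSTN (ENSG00000133110.15, minus strand of chromosome 13, 37562583 to 37598844) was at 42.9 ± 1.93 against 65.2 ± 4.02 CPM. The basement membrane collagen COL4A1 was lower at -0.30 ± 0.024 and the fibrillar collagen COL5A2 at -0.22 ± 0.019, while TIMP3, an inhibitor of matrix proteases, was higher at 0.32 ± 0.026. Cholesterol genes were lower in 15 of 24 cases (22 adjusted over the list alone; camera adjusted p = 1.31e-21, lost at adjusted p = 0.108 with an estimated correlation), among them LSS (-0.28 ± 0.028), HMGCS1 (-0.27 ± 0.031) and SREBF2 (-0.15 ± 0.023). Amino acid and endoplasmic reticulum stress genes were lower in 7 of 24 cases (13 adjusted over the list alone), including the serine synthesis enzymes PHGDH (-0.11 ± 0.024) and PSAT1 (-0.18 ± 0.038), with adjusted p = 0.159 with an estimated correlation. Hypoxia genes were lower in 5 of 17 cases and higher in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), including SLC2A3 (-0.21 ± 0.029) and VEGFA (-0.25 ± 0.034). Complement had 2 of 13 lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation), with C1R at -0.42 ± 0.037 and C1S at -0.40 ± 0.047. TGF-beta and YAP targets had 7 of 22 lower and 5 higher (11 and 6 adjusted over the list alone; adjusted p = 0.343 with an estimated correlation), TAGLN at -0.21 ± 0.025. Oxidative phosphorylation had 1 of 40 higher, ATP5MC3 at 0.08 ± 0.024 (0 adjusted over the list alone; 3 at an unadjusted p under 0.05), with adjusted p = 0.66 with an estimated correlation. G2/M genes had 0 of 28 called by edgeR (4 at an unadjusted p under 0.05, and 0 by DESeq2, limma-voom and the TPM fit), and MKI67 had 0.04 (adjusted p = 0.628).

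Between recovery and vehicle 1074 genes passed, 547 higher and 527 lower, of which 14 rose and 10 fell at least 2-fold and 7 changed beyond 1.5-fold by glmTreat. On log2 TPM the count was 118 (76 higher and 42 lower) and with the gene length offset 183. Of 51 genes named as changed here, 27 and 32 stayed called in those fits, OAS2, MX1, OASL, SFRP1 and POSTN in both. Without the library vehicle 1 the count was 624, without recovery 2 it was 701 and without recovery 3 it was 713. Vehicle cells are labelled 24 h, so recovery cells differ from them in time in culture as well as in the pulse.

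**Figure D4:**
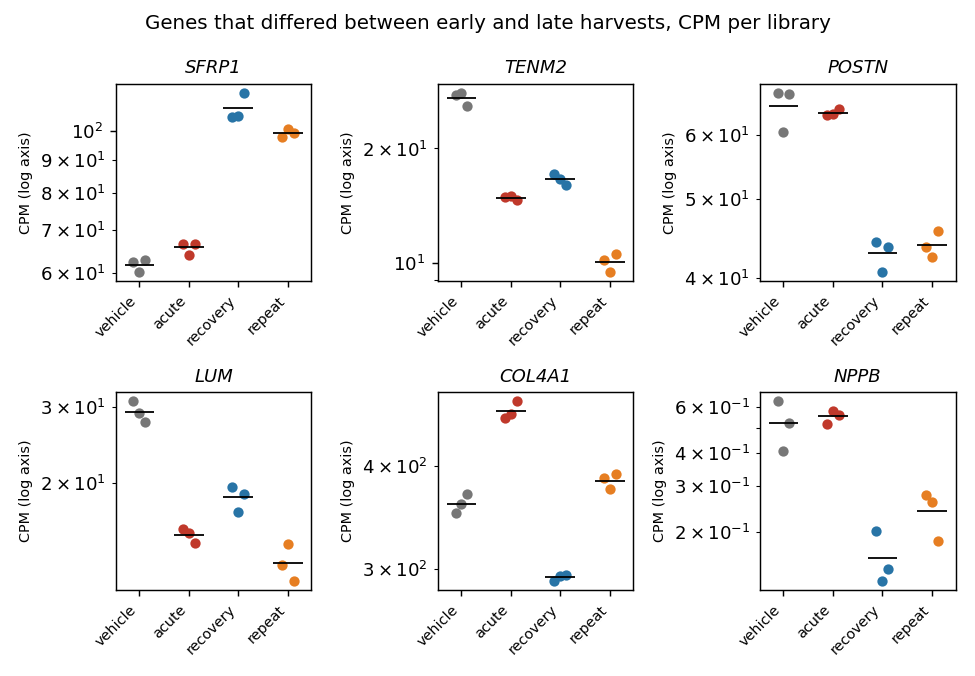
CPM on log axes, scaled per gene, of SFRP1, TENM2, POSTN, LUM, COL4A1 and NPPB in the 4 groups; points are libraries (n = 3) and lines are means. SFRP1 is higher, and POSTN and TENM2 lower, in recovery than in vehicle and in repeat than in acute.

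How much of the acute rise remained was then counted. Of the 4050 genes higher in acute cells, 405 (10%) were also higher in recovery, and of the 386 that rose at least 2-fold, 90 (23.3%) were. Independent lists of these sizes would share 122.3 and 11.7 genes. For falls, 403 of 3890 were shared against 113.1 for independent lists. Fold changes of acute and recovery against vehicle correlated across the 18119 genes (r = 0.433, genes are not independent replicates). In 20 simulations with no group changed, r had a mean of 0.0506 and was at most 0.129. The covariance was 0.0802, against 0.00180 on average in those simulations. The simulated groups were drawn around the observed vehicle means, so the simulations leave out the error that shared vehicle libraries bring. How much of the correlation and of the shared calls comes from this sharing is therefore not known. Among 182 genes that rose at least 2-fold to at least 5 CPM, a median of 3.31% of the rise remained, and among the 76 of them called higher in recovery 9.71%. Shares remaining for interferon-stimulated genes were 30.2% ± 2.31 (SE) for OASL and 1.42% for OAS2, and 0.537% for MX1. The surface proteins LYPD1 (59.5%) and ITGA2 (53.5%) had the largest shares of the 182. Both were also higher in repeat than in acute cells by edgeR (0.321, adjusted p = 0.00459, and 0.385, adjusted p = 0.0195). Vehicle cells are labelled 24 h, so a share may hold a difference in time in culture as well as a remainder of the rise. On log2 TPM 69 genes were higher in both comparisons, with the gene length offset 90, and without vehicle 1 259.

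The later pulse was read by comparing repeat with recovery cells. By the stated times recovery cells were held 5 days and repeat cells 4 days before their next pulse, so the state right before that pulse was not sampled. Antiviral genes led among those with a gene symbol and at least 5 CPM. IFI44L rose by 7.97 ± 0.062, BST2 by 7.69 ± 0.097, IFI27 by 7.62 ± 0.082, OAS1 by 7.14 ± 0.051, MX2 by 6.81 ± 0.095 and MX1 by 6.71 ± 0.071. IRF7 rose by 3.23 ± 0.047, ISG15 by 3.40 ± 0.031 and USP18 by 5.76 ± 0.082. TNFRSF10D fell by 3.09 on the log2 scale (SE 0.038), and DHRS3 (-2.48 ± 0.103), COLEC12 (-1.96 ± 0.112) and LINC00641 (-1.67 ± 0.101) followed. All 60 interferon-stimulated genes rose, as did all 22 MHC class I genes (TAP1 2.78 ± 0.029), also adjusted over the list alone, and these held with an estimated correlation at adjusted p = 0.00133 and adjusted p = 0.00145. Of 21 NF-kB genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; LIF 1.09 ± 0.049; adjusted p = 0.0315 with an estimated correlation), and of 24 cell death genes 16 rose and 4 fell (16 and 4 adjusted over the list alone; PMAIP1 1.13 ± 0.032; adjusted p = 0.0315 with an estimated correlation). Complement had 8 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; C1S 1.99 ± 0.041; adjusted p = 0.0861 with an estimated correlation), TGF-beta and YAP targets 11 of 22 higher and 4 lower (12 and 4 adjusted over the list alone; INHBA 1.18 ± 0.031; adjusted p = 0.15 with an estimated correlation), and heat shock 8 of 13 higher and 2 lower (9 and 2 adjusted over the list alone; DNAJA1 0.50 ± 0.023; adjusted p = 0.209 with an estimated correlation). G2/M genes fell in 26 of 28 cases (26 adjusted over the list alone; TOP2A -0.40 ± 0.022, KIF20A -0.41 ± 0.022; adjusted p = 0.00169 with an estimated correlation), and MKI67 had -0.36 ± 0.031. Cholesterol genes fell in 20 of 24 cases (20 adjusted over the list alone, LSS -0.65 ± 0.029, camera adjusted p = 0.209 with an estimated correlation). Mitochondrially encoded mRNAs fell in 12 of 13 (12 adjusted over the list alone, MT-CO3 -0.53 ± 0.022, camera adjusted p = 0.175 with an estimated correlation). All genes with an MT- symbol held 4.51% ± 0.11 of counts in repeat libraries.

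The test called 7546 genes between repeat and recovery, 3824 higher and 3722 lower (3311 and 4243 with upper quartile scaling), and 336 rose and 135 fell at least 2-fold. Of the 4050 genes higher after the first pulse, 3095 (76.4%) rose again, and of the 3890 lower 3021 (77.7%) fell again, while 8 and 2 went the other way. These comparisons share no library. MX1, TNFRSF10D and the other genes named here kept their calls on log2 TPM, where 3824 genes passed, and with the gene length offset, where 3963 did. Against vehicle, repeat cells had 8393 genes called, 4244 higher and 4149 lower (3744 and 4633 with upper quartile scaling), with MX2 (9.70 ± 0.128), OAS1 (9.37 ± 0.064) and IFI44L (8.53 ± 0.065) highest and, among genes with a symbol and at least 5 CPM, TNFRSF10D (-3.25 ± 0.038), DHRS3 (-2.94 ± 0.101) and COLEC12 (-2.11 ± 0.111) lowest. On log2 TPM 4651 genes passed and with the gene length offset 4825. All 60 interferon-stimulated genes were higher, also adjusted over the list alone.

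**Figure D5:**
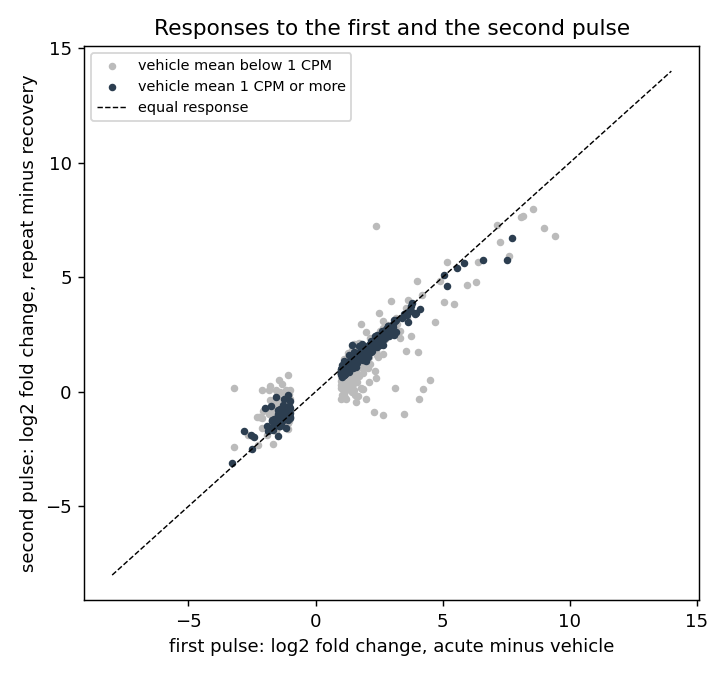
Log2 fold change at the later pulse (repeat against recovery) over that at the first (acute against vehicle) for the 588 genes called and changed at least 2-fold at the first; dark points had a vehicle mean of at least 1 CPM, grey points less, and the dashed line marks equal responses. Dark points lie close to the line, grey points scatter more, and the strongest rises lie mostly below it.

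Whether the responses to the pulses differed in log2 fold change was tested with the interaction. On the log2 scale several antiviral genes rose less from recovery than they had from vehicle. The levels reached were not lower as a rule. Of the 22 interferon-stimulated genes lower in the interaction, 20 ended at or above their acute level. OAS2 had an interaction of -1.77 ± 0.065 (adjusted p = 1.35e-16), with 587 ± 4.16 CPM after the first pulse and 625 ± 10.0 after the later one, against 3.15 in vehicle and 11.4 in recovery. MX2 (-2.61 ± 0.357, adjusted p = 0.015), OAS1 (-1.83 ± 0.181), RSAD2, an antiviral radical SAM enzyme (-1.65 ± 0.215), CMPK2 (-1.51 ± 0.213), MX1 (-1.02 ± 0.145), IFIT3 (-0.64 ± 0.050), OASL (-0.63 ± 0.061), HERC6 (-0.59 ± 0.063) and HLA-F (-0.58 ± 0.122) followed. RSAD2 and CMPK2 overlap at their starts on opposite strands, and whether counting used strand is not given in the sources used here, so their values are uncertain; both turned positive and uncalled on log2 TPM (0.31 and 0.16). DESeq2 did not call RSAD2, CMPK2, HERC6 or HLA-F, some or all of which had no adjusted p in it. MX2 and MX1 lost their calls with a surrogate variable and with depth as a covariate, and HLA-F by limma-voom and with depth. With the gene length offset OAS1, CMPK2, IFIT3, HERC6 and HLA-F lost theirs, and on log2 TPM every called gene of this paragraph but OAS2, OASL and ISG15. Of the 60 interferon-stimulated genes 22 were lower in the interaction (33 adjusted over the list alone) and 0 higher by edgeR, DESeq2, limma-voom and the TPM fit, and the list held with an estimated correlation (adjusted p = 0.0199). OAS3 (-0.56 ± 0.039), IFI44 (-0.47 ± 0.043) and ISG15 (-0.53 ± 0.044) were among them, while USP18 (-0.84 ± 0.203, adjusted p = 0.118) did not pass.

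Other lists with a camera call were smaller. MHC class I had 3 of 22 lower (7 adjusted over the list alone; TAP2 -0.17 ± 0.034; adjusted p = 0.0892 with an estimated correlation), nucleic acid sensing 2 of 20 lower (7 lower and 1 higher adjusted over the list alone; RIGI -0.54 ± 0.065; adjusted p = 0.116 with an estimated correlation), interferon-gamma-type genes 1 of 20 lower (4 lower and 1 higher adjusted over the list alone; APOL6 -0.31 ± 0.057; adjusted p = 0.366 with an estimated correlation) and retroelement restriction factors 1 of 13 lower (2 adjusted over the list alone; ZC3HAV1 -0.23 ± 0.039; adjusted p = 0.0638 with an estimated correlation). Of 24 cholesterol genes 5 had a positive interaction, that is a smaller fall at the later pulse (15 adjusted over the list alone; CYP51A1 0.16 ± 0.036, HMGCS1 0.22 ± 0.044, IDI1 0.16 ± 0.035, LSS 0.18 ± 0.040; adjusted p = 0.128 with an estimated correlation). These 4 were not called with a surrogate variable or with depth as a covariate. Amino acid and endoplasmic reticulum stress had 1 of 24 higher (4 adjusted over the list alone; PHGDH 0.14 ± 0.033; adjusted p = 0.277 with an estimated correlation), and complement 2 of 13 (3 adjusted over the list alone; adjusted p = 0.363 with an estimated correlation), C1R (0.28 ± 0.048) and C1S (0.29 ± 0.059). Among genes with a symbol and at least 5 CPM the highest interactions were in LUM (0.46 ± 0.091), the deiodinase DIO2 (0.39 ± 0.093), CADM4 (0.35 ± 0.079), the proteoglycan DCN (0.33 ± 0.067), the clock-linked repressor BHLHE40 (0.32 ± 0.058), PIM1 (0.28 ± 0.055), TMEM41B (0.25 ± 0.059) and PRORP (0.25 ± 0.059). These 8 were called neither on log2 TPM, with the gene length offset nor with depth as a covariate, and LUM alone of them was called with a surrogate variable. DESeq2 did not call them either, but most of them had no adjusted p in it.

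The interaction passed for 118 genes, 40 higher and 78 lower, and 75 of the 78 had risen at the first pulse. Because the interaction subtracts the first response, part of this overlap is built in. On log2 TPM 3 genes passed, OAS2, ISG15 and OASL, with the gene length offset 13, by DESeq2, under its own filtering in place of the count filter, 232 and without a count filter 333. With a surrogate variable 39 passed and 3 of these were higher, and with depth as a covariate 33 passed and 2 were higher. Both covariates partly followed the groups. Mean depth was 55.2 M in repeat against 46.3 M in recovery, 46.6 M in acute and 48.8 M in vehicle libraries. The surrogate variable was -0.256, -0.0835 and -0.362 in the repeat libraries. These fits therefore cannot tell the covariates from the later pulse. Leaving out 1 library gave 68 without vehicle 1, 64 without vehicle 2, 64 without acute 2, 54 without acute 3, 62 without recovery 1, 66 without recovery 2, 57 without recovery 3, 328 without repeat 1 and 65 without repeat 3. Over the 588 genes called and changed at least 2-fold at the first pulse, the slope of the later response on the first was 0.777 (r = 0.922 and rho = 0.890 across genes, which are not independent replicates; median difference -0.07). Over the 285 of them with a vehicle mean of at least 1 CPM the slope was 0.875, and with no count filter it was 0.411. Genes were chosen by the first response, and error in it lowers the slope even where responses are equal.

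The levels reached after each pulse were compared directly, repeat with acute. Interferon-stimulated genes ended at about the same level, with a median log2 fold change of -0.001 over the 60. RSAD2 (ENSG00000134321.13, plus strand of chromosome 2, 6865557 to 6898239) was higher in repeat cells, at 30.8 ± 0.621 against 16.6 ± 1.47 CPM (0.89 ± 0.062, adjusted p = 2.59e-09), as were CMPK2 (0.52 ± 0.048), GBP4 (0.51 ± 0.088), OAS1 (0.40 ± 0.027) and LY6E (0.25 ± 0.027). ISG15 (-0.003) did not differ by the test, and STAT2 was lower (-0.15 ± 0.031). Over the list 9 were higher and 2 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.115). MHC class I had 4 of 22 higher and 1 lower (5 and 1 adjusted over the list alone; PSMB9 0.28 ± 0.034, HLA-F 0.34 ± 0.058; adjusted p = 0.339 with an estimated correlation).

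Genes that differed between recovery and vehicle tended to differ the same way here. SFRP1 was higher by 0.59 ± 0.031, at 99.2 ± 1.44 against 65.8 ± 1.51 CPM, and the urokinase gene PLAU by 0.58 ± 0.053. TENM2 (-0.56 ± 0.055), OLR1 (-0.54 ± 0.117), POSTN (-0.54 ± 0.040), AGAP6 (-0.53 ± 0.116), LYPD6B (-0.47 ± 0.073) and TGFB2 (-0.43 ± 0.062) were lower. Fibroblast and matrix genes were lower in 14 of 32 cases and higher in 4 (18 and 9 adjusted over the list alone; camera adjusted p = 9.75e-07), with COL4A1 at -0.28 ± 0.023, COL4A2 at -0.19 ± 0.020 and COL1A1 at -0.24 ± 0.026; the call was lost at adjusted p = 0.213 with an estimated correlation. TGF-beta and YAP targets had 7 of 22 lower and 0 higher by edgeR (7 and 2 adjusted over the list alone; 9 at an unadjusted p under 0.05), with the contractile genes TAGLN (-0.23 ± 0.024) and MYL9 (-0.16 ± 0.021) lower, at adjusted p = 0.276 with an estimated correlation. NRF2 targets rose in 4 of 18 cases (7 adjusted over the list alone): AKR1C1 (0.56 ± 0.060), NQO1 (0.15 ± 0.023), GCLM (0.14 ± 0.025) and FTH1 (0.08 ± 0.022), and this list held with an estimated correlation at adjusted p = 0.0234. AKR1C1 and AGAP6 have near-identical relatives and are uncertain. Oxidative phosphorylation had 2 of 40 higher (4 adjusted over the list alone; UQCRB 0.12 ± 0.024, NDUFA1 0.13 ± 0.034; adjusted p = 0.339 with an estimated correlation). Autoantigens had 2 of 18 higher (7 adjusted over the list alone; XRCC6 0.08 ± 0.022, SSB 0.07 ± 0.021; adjusted p = 0.276 with an estimated correlation), G1/S 2 of 25 higher (4 higher and 1 lower adjusted over the list alone; RRM2 0.07 ± 0.020; adjusted p = 0.276 with an estimated correlation) and hypoxia 2 of 17 lower (4 lower and 1 higher adjusted over the list alone; LOX -0.18 ± 0.022, SLC2A3 -0.12 ± 0.029; adjusted p = 0.353 with an estimated correlation). NPPB was lower (-1.18 ± 0.313, adjusted p = 0.0291), GATA6 was lower (-0.25 ± 0.035), ACTN2 was higher (0.89 ± 0.134) and MKI67 was lower (-0.13 ± 0.031). DESeq2 called neither NPPB nor ACTN2, limma-voom did not call MKI67, and NPPB and MKI67 lost their calls with a surrogate variable and with depth as a covariate. AGAP6, FTH1, NDUFA1, XRCC6, SSB and RRM2 lost theirs in both of these fits as well, UQCRB with depth and OLR1 with the surrogate variable.

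Between repeat and acute 761 genes passed, 321 higher and 440 lower, with 4 and 8 at least 2-fold and 0 beyond 1.5-fold by glmTreat (69 at its unadjusted p under 0.05). Of the 547 genes higher in recovery than in vehicle 130 were higher here, where independent lists would share 9.7, and of the 527 lower 152 were lower (12.8). Opposite directions held 0 and 1 genes. Without acute 1, 2 or 3 the count was 502, 377 or 336, and without repeat 1, 2 or 3 it was 1217, 360 or 428. On log2 TPM 6 genes passed, RSAD2, SFRP1, COL4A2 and COL1A1 among them, and with the gene length offset 17; of the 36 genes named as changed here, 4 and 7 stayed called. With a surrogate variable 366 passed and with depth as a covariate 345. Repeat libraries held 55.2 M counts on average and acute libraries 46.6 M.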

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

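The later pulse differed from the first by a direct test of the difference, (repeat minus recovery) minus (acute minus vehicle), in 118 genes and 11 gene lists. The interaction and its lists were planned, and the explanations weighed here were tested only after the results were seen. Antiviral genes made up the strongest part. MX2 (-2.61), OAS1 (-1.83), OAS2 (-1.77), RSAD2 (-1.65), CMPK2 (-1.51), MX1 (-1.02), IFIT3 (-0.64), OASL (-0.63), HERC6 (-0.59), HLA-F (-0.58), OAS3 (-0.56), RIGI (-0.54), ISG15 (-0.53), IFI44 (-0.47), APOL6 (-0.31), ZC3HAV1 (-0.23) and TAP2 (-0.17) had a lower log2 change at the later pulse. LUM (0.46), DIO2 (0.39), CADM4 (0.35), DCN (0.33), BHLHE40 (0.32), C1S (0.29), C1R (0.28), PIM1 (0.28), TMEM41B (0.25), PRORP (0.25), HMGCS1 (0.22), LSS (0.18), CYP51A1 (0.16), IDI1 (0.16) and PHGDH (0.14) had a higher one. On log2 TPM all these genes but OAS2, OASL and ISG15 lost their calls. With the gene length offset all the higher ones and OAS1, CMPK2, IFIT3, HERC6, HLA-F, TAP2, APOL6 and ZC3HAV1 did, and with depth as a covariate all the higher ones and MX2, MX1, HLA-F and TAP2.

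Camera called 6 lists lower or mostly lower: interferon-stimulated genes (adjusted p = 1.25e-35), MHC class I (2.42e-07), nucleic acid sensing (0.000349), retroelement restriction (0.000699), interferon-gamma-type genes (0.0178) and mitochondrially encoded mRNAs (0.0393). It called 5 higher: cholesterol (3.74e-18), amino acid and endoplasmic reticulum stress (3.63e-05), G1/S (0.000654), NRF2 targets (0.0152) and complement (0.0285). Interferon-stimulated genes alone passed with an estimated correlation (adjusted p = 0.0199). In G1/S, edgeR called 0 of 25 (3 higher adjusted over the list alone, 6 at an unadjusted p under 0.05, and 2 by DESeq2; adjusted p = 0.128 with an estimated correlation). For NRF2 targets it called 0 of 18 (2 higher adjusted over the list alone, 6 at an unadjusted p under 0.05, and 1 by DESeq2; adjusted p = 0.128 with an estimated correlation). Of the 13 mitochondrially encoded mRNAs it called 0 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, and 2 lower by DESeq2; adjusted p = 0.666 with an estimated correlation). limma-voom and the TPM fit called 0 in these 3 lists.

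The smaller log2 rise of interferon-stimulated genes at the later pulse was weighed first. Near-zero counts in vehicle cells are argued against as the whole cause, since 18 of the 22 genes called lower had a vehicle mean of at least 1 CPM. The interaction is by arithmetic the change from acute to repeat (list median -0.001) less that from vehicle to recovery (0.17), so these values place the difference in recovery against vehicle, not in the level reached. They test no cause, and the level right before the later pulse was not measured, since recovery cells were held 5 days and repeat cells 4. MX2, OAS1, RSAD2 and CMPK2 had under 1 CPM in vehicle, so their interaction values rest on few counts.

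The interferon-stimulated genes above vehicle in recovery came next. Reads carried over from pulsed libraries would leave every gene the same share of its rise, but shares ranged from 0.318% to 30.2% over the 28 called genes, and 22 of these lay over 2 SE above the median share of 1.07%. Carry-over is thus argued against as the whole cause for those 22 genes. MX1 (0.537%) was not among them, so this count does not bear on it. Time in culture cannot be told apart from the earlier pulse (median 0.174), because vehicle cells carry only a 24 h label. A lasting effect of interferon on OASL and OAS2 may be part of it, as a hypothesis.

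Matrix genes that differed in both late-harvested groups, mostly lower (17 lower and 7 higher in recovery), were the last pattern, and the list calls were lost with an estimated correlation (adjusted p = 0.0921 and 0.213). Library depth was not settled by signs. Recovery libraries were 2.47 M below vehicle, within the vehicle SD of 6.93 M, and repeat libraries 8.65 M above acute. Depth thus predicted no clear opposite sign. All 24 matrix genes called in recovery had the same sign in repeat against acute, which cannot decide the question. With depth as a covariate 50 of the 51 genes named as changed in recovery stayed called. The 1 lost, ATP5MC3, is not a matrix gene. POSTN and COL4A1 may have fallen with time in culture, which cannot be told apart from the pulse (r = 0.625 across the list). No vehicle culture of the later days is in the design.

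The 12 libraries were also split in other ways. For each pair of groups the 6 libraries make 10 splits, too few for a share under 0.05 (1 of the 10, the real one, gave as many genes). Real counts and the highest of the other splits were 7940 and 0 for acute against vehicle, 1074 and 1 for recovery against vehicle, 8393 and 0 for repeat against vehicle, 7448 and 1 for recovery against acute, 7546 and 0 for repeat against recovery, and 761 and 0 for repeat against acute. Each other split mixed both groups, so a real difference widens the spread within its parts and low counts follow. These counts are therefore not a chance level. For the interaction 4 of 60 relabellings gave as many genes as the real 118, with up to 287, so chance is not excluded by this count. The 3 others all kept vehicle apart from recovery and relabelled the pulsed libraries, so they still held the difference between vehicle and recovery. The highest of those that mixed vehicle with recovery was 10, and such mixing widens the spread. The share of 4 in 60 is therefore not a chance level.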

How the results depend on the processing

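The counts of genes moved most when a change of 1.5-fold was required or when gene length was handled otherwise, and the cause was not tested. The gene length offset, depth as a covariate and the vehicle minimum of 1 CPM were chosen after the results were seen, and the other alternatives were planned. Values are given in the order acute against vehicle, recovery against vehicle, repeat against vehicle, recovery against acute, repeat against recovery, repeat against acute and the interaction. On log2 TPM 4344, 118, 4651, 3836, 3824, 6 and 3 genes passed, and with the gene length offset 4405, 183, 4825, 3946, 3963, 17 and 13; with this offset the biological coefficient of variation was 11.2% instead of 2.67%. Beyond 1.5-fold by glmTreat 548, 7, 666, 382, 424, 0 and 3 passed (for the 0, 69 at an unadjusted p under 0.05). At an adjusted p under 0.01 the recovery count was 588, the repeat against acute count 254 and the interaction count 40. A surrogate variable gave 366 for repeat against acute and 39 for the interaction, and depth as a covariate 345 and 33. Both covariates partly followed the groups, so these lower counts may come from that overlap. The interaction count was 333 with no filter, and 232 by DESeq2, which also replaced the count filter by its own. Upper quartile or RLE scaling, limma-voom and a stricter filter left every count of genes within 1.5 times, though upper quartile scaling turned the larger direction in acute against vehicle (3462 higher and 4478 lower), repeat against vehicle (3744 and 4633), recovery against acute (4329 and 3149) and repeat against recovery (3311 and 4243).

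With an estimated correlation camera called 6 lists for acute, 0 for recovery (8 at an unadjusted p under 0.05, and 16 by fry) and 6 for repeat against vehicle, 11 for recovery against acute, 9 for repeat against recovery, 1 for repeat against acute and 1 for the interaction. Fry called 27 for acute and 26 for repeat against vehicle, 27 for recovery against acute and 25 for repeat against recovery. Genes higher in both acute and recovery numbered 69 on log2 TPM, 90 with the gene length offset and 37 among those that rose at least 4-fold in acute cells. The slope of the later response on the first was 0.693 by DESeq2, 0.745 by limma-voom, 0.411 with no filter, 0.864 with a stricter filter, 0.896 on log2 TPM, 0.759 with a surrogate variable, 0.696 with the gene length offset, 0.772 with depth as a covariate and 0.875 over genes with a vehicle mean of at least 1 CPM, so its distance from 1 depended on genes with few counts.

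Leaving out 1 library at a time gave 7018 to 8080 genes for acute against vehicle, 624 (without vehicle 1) to 1160 (without repeat 1) for recovery against vehicle, 7453 to 8404 for repeat against vehicle, 6621 to 7597 for recovery against acute, 6791 to 7520 for repeat against recovery, 336 (without acute 3) to 1217 (without repeat 1) for repeat against acute and 54 (without acute 3) to 328 (without repeat 1) for the interaction. Recovery against vehicle also moved over 1.5 times without recovery 2 (701) and recovery 3 (713). Repeat against acute did so without acute 1 (502), acute 2 (377), repeat 2 (360) and repeat 3 (428), and the interaction without vehicle 1 (68), vehicle 2 (64), acute 2 (64), recovery 1 (62), recovery 2 (66), recovery 3 (57) and repeat 3 (65). Lists called ranged over 15 to 15, 9 to 13, 13 to 14, 15 to 15, 14 to 14, 8 to 10 and 9 to 13. The persistence count ranged from 259 (without vehicle 1) to 428 (without repeat 1) and the slope from 0.647 (without acute 1) to 0.752 (without repeat 3).

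Direction turned for 4 named genes: IFNAR1 in acute cells was 0.083 on log2 TPM and 0.069 with the gene length offset, TIE1 -0.26 and -1.14, and the interactions of RSAD2 and CMPK2 were 0.31 and 0.16 on log2 TPM. A block for replicate number gave 7983, 1125, 8409, 7494, 7564, 855 and 160 genes, and whether the numbers pair the libraries is open: residuals of the same number correlated at -0.082 to 0.076 and those of other numbers at -0.103 to 0.107, 7 of 12 libraries were best matched by their own number, and the same-number values were all positive between vehicle and acute (0.055 to 0.076) and between vehicle and repeat (0.025 to 0.055).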

Other observations

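Several gene groups in acute cells moved without a common direction. Energy metabolism was mixed: the hexokinase HK2 rose by 0.67 ± 0.029 and LDHA changed by -0.40 ± 0.021, with 6 of 20 glycolysis genes higher and 9 lower (the same counts adjusted over the list alone; camera adjusted p = 0.511). The respiratory chain subunits UQCRC1 (-0.18 ± 0.024) and NDUFA2 (-0.33 ± 0.044) fell, in a list of 40 nuclear genes of oxidative phosphorylation with 9 higher and 10 lower (9 and 11 adjusted over the list alone; 0.705). CPT1B, which carries fatty acids into mitochondria, rose by 0.73 ± 0.070 and the fatty acid binder FABP3 fell (-1.77 ± 0.241), with 5 of 21 fatty acid oxidation genes higher and 8 lower (the same adjusted over the list alone; 0.672). The chaperones PDIA4 (0.48 ± 0.021) and HSPA5 (0.30 ± 0.019) rose, in a stress list with 9 of 24 higher and 9 lower (the same adjusted over the list alone; 0.89). The p53 targets ZMAT3 (-0.82 ± 0.049) and AEN (0.44 ± 0.030) parted, 7 of 18 higher and 5 lower (7 and 6 adjusted over the list alone; 0.886). In hypoxia genes BNIP3L fell (-0.84 ± 0.025) and P4HA2 rose (0.53 ± 0.026), 5 of 17 higher and 8 lower (the same adjusted over the list alone; 0.511). The cystine importer SLC7A11 fell (-0.73 ± 0.048), with 4 of 18 NRF2 targets higher and 7 lower (the same adjusted over the list alone; 0.632).

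Markers of cell identity were few. Of 32 cardiomyocyte markers 15 were measured, 6 higher and 3 lower (6 and 4 adjusted over the list alone; 0.672): tropomyosin TPM1 (0.34 ± 0.021) and the exchanger SLC8A1 (0.41 ± 0.043) rose and the gap junction gene GJA1 fell (-0.17 ± 0.023). NPPB did not pass in acute cells (0.07 ± 0.29, adjusted p = 0.887). Endothelial markers had 1 of 7 higher (1 adjusted over the list alone; 0.753), TIE1 at 0.68 ± 0.223, which turned to -0.26 on log2 TPM and -1.14 with the gene length offset. The lysosomal gene CD68 rose (1.30 ± 0.030), in a leukocyte list with 1 of 5 higher and 1 lower (the same adjusted over the list alone; 0.614). KRT18 fell (-0.38 ± 0.022) and KRT14 rose (1.47 ± 0.155), with 1 of 8 epithelial markers higher and 4 lower (the same adjusted over the list alone; 0.478). Replication-dependent histones had 3 of 9 higher (3 adjusted over the list alone; 0.511), H1-2 at 0.50 ± 0.060, although such transcripts lack poly(A) tails. Lupus autoantigens had 4 of 18 higher and 6 lower (the same adjusted over the list alone; 0.753), with the antibody receptor TRIM21 at 2.40 ± 0.047 and RPLP0 at -0.24 ± 0.022. In tryptophan and NAD metabolism WARS1 rose (0.74 ± 0.025) and NNMT fell (-1.28 ± 0.055), 4 of 14 higher and 5 lower (4 and 6 adjusted over the list alone; 0.89). The noncoding RNAs BISPR (5.07 ± 0.223) and PSMB8-AS1 (1.41 ± 0.079) rose, 3 of 8 higher and 1 lower (the same adjusted over the list alone; 0.319), and both lie beside or across interferon-stimulated genes, so they are uncertain where strand was not used. MHC class II had 2 of 7 higher (2 adjusted over the list alone; 0.437), with CTSS at 1.63 ± 0.164, and negative regulators of interferon signalling had 6 of 16 higher and 7 lower (6 and 8 adjusted over the list alone; 0.753), with the phosphatase PTPN11 at -0.52 ± 0.022.

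A few comparisons add detail. In repeat against acute, JAK-STAT components had 0 of 19 higher and 1 lower by edgeR (0 and 3 adjusted over the list alone, 7 at an unadjusted p under 0.05, and 0 higher by DESeq2 and limma-voom), with adjusted p = 0.276 with an estimated correlation. Mitochondrially encoded mRNAs had 0 of 13 called there (1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 lower by DESeq2, 0 by limma-voom), with adjusted p = 0.694 with an estimated correlation. Among the 1074 genes that differed between recovery and vehicle, the change from acute to repeat had the same sign in 86.0% (rho = 0.815; genes are not independent replicates). A vehicle culture kept for 6 days and harvested with the recovery and repeat cells would separate time in culture from the pulse for SFRP1, POSTN and OASL.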
